A study of Drosophila melanogaster with 9 samples.

How the data were processed

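Gene expression was measured in whole heads of Drosophila melanogaster of the genotype wild type Canton-S w1118 (iso1CJ), with 200 heads per sample, collected shortly after lights on (ZT0.5-2). Flies had been kept in a group for 7 days, alone for 7 days or alone for 1 day, with 3 samples per condition. The labels give neither the sex of the flies nor their age at collection. Libraries were made with the TruSeq stranded mRNA LT kit. The authors demultiplexed with bcl2fastq 2.20, aligned with STAR 2.4.2a and counted reads per gene with featureCounts, per the submitters' processing notes. The featureCounts version, the genome build, the annotation release and the strand and multi-mapping settings are not given in the sources used here. The deposited values were counts: whole numbers of reads per gene and library, neither normalised nor pooled over replicates, with the summed exon length of each gene beside them. Gene symbols and positions were taken from the BDGP6 annotation of Ensembl by gene identifier. Of 17490 genes in the deposited counts, 17288 had a symbol and 17144 had the same span in that annotation. Exons of 4520 genes overlapped an exon on the other strand, so part of their reads could belong to the overlapping gene if counting ignored the strand.

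Library totals ranged from 39698143 to 53514747 counts. A count of 0 in a library allows an abundance of up to 3 counts of that total, which covers counting error only.

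The counts were fitted with edgeR 4.0.16 in R 4.3.3, using the filterByExpr filter on the groups, TMM normalization and the quasi-likelihood test, with all 9 libraries in a single fit and the group as the only term. This left 12963 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no minimum fold change. The comparisons were 7 days alone against group, 1 day alone against group, 7 days against 1 day alone, and an F test of any difference among the 3 groups. Standard errors (SE) were derived from the test, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Abundances are given as CPM, the counts of a gene relative to the library total scaled with the TMM factors, as mean ± SD of 3 libraries.

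In all, 34 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 3 tested members. The same test was run with the correlation estimated from the data. In addition fry, which tests the members of a list without setting them against the other genes, was run without a body tissue term. It was run for direction and as a mixed test, which counts changes of members either way. For each list, members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. The gene lists, the comparisons, the tests, the rule for named genes and the settings of the first list of alternatives below were chosen before the data were examined.

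Named genes were, for each comparison, the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups; the 10 further called genes with the lowest p; and up to 4 called members of each list. Genes beyond about 30 per comparison were left out in order of p. Lst, Dsk, fit, Cyp6a20, Obp69a, to, Hr38, Thor, per and tim were named whatever their values. Lst and Dsk were recalled from the publication on this series, so they are not independent picks.

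The first alternatives were RLE and upper quartile normalization, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a block for the replicate number, only the libraries of the groups compared, the estimated correlation for the lists, and leaving out each library in turn. Alternatives chosen after seeing the data were a term in the model for the presence of body tissue (gut and male tract transcripts summing to over 50 CPM), and leaving out the genes whose abundance differed by at least 0.5 log2 units with body tissue. Further ones of this kind were fitting only the libraries with or only those without body tissue, and subtracting a fitted trend with gene length in each library. The subtraction left part of the trend. The Spearman rho of fold changes with length went from -0.27 to -0.15 at 7 days against group and from -0.41 to -0.19 at 1 day against group. The replicate numbers did not pair the samples: among genes without a body effect, deviations from the group mean correlated between equally numbered libraries at r from -0.23 to 0.04. A block for the replicate number was therefore kept as an alternative only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.

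The tests were tested on simulated counts of 12963 genes, drawn from the fitted means with the body tissue of each library kept and no group difference, with the spread left after the body tissue term. At each fold 50 genes were changed, taken from those with at least 5 CPM and 10 counts in every library. For 7 days alone against group, 5, 23, 46 and 49 genes were recovered at folds of 1.25, 1.5, 2 and 3, with 0 false calls. For 1 day against group the numbers were 4, 24, 45 and 49, with 1 false call, and for 7 days against 1 day they were 3, 19, 42 and 49, with 0 false calls. With the body tissue term, 42, 42 and 40 genes were recovered at a fold of 1.5 in these comparisons, with 16, 22 and 17 false calls over all folds, so the counts with this term hold some more false calls than the threshold allows. For the lists, 1 list of 48 genes was raised 1.3-fold in 10 simulated sets, again of 12963 genes. With the preset correlation the raised list was called in 10 of 10 sets in each comparison, with on average 6.1, 4.6 and 0.1 of the 33 unchanged lists called too. With the estimated correlation it was called in 1, 0 and 9 of 10 sets, and with both the body tissue term and the estimated correlation in 10 of 10 sets in each comparison, with 0 unchanged lists called. Apart from body tissue the simulated genes varied independently, while the real oxidative phosphorylation genes had an estimated correlation of 0.857. The simulated sets therefore do not show how the list tests behave on correlated genes. A call of a list with the preset correlation alone is weak evidence in each comparison, as splits of the libraries other than the real one gave as many lists (below).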

Results

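Transcripts of gut and male tract were present in 5 of the 9 head libraries, in all 3 groups: 1 of 3 group libraries (replicate 2), 2 of 3 libraries of 1 day alone (replicates 1 and 2) and 2 of 3 libraries of 7 days alone (replicates 1 and 3). Markers of these tissues (gut proteases and lysozymes, male germline and accessory gland genes) summed to 775 to 1721 CPM in these 5 libraries and to 2.47 to 5.46 CPM in the other 4. Cyp4g1, a cytochrome P450 of the oenocytes of the body wall, was at 542 to 1692 CPM in the 5 and at 0.866 to 1.58 CPM in the 4. The first principal component followed this difference and held 94.3% of the variance. Of 12963 genes tested, 2977 differed by at least 0.5 log2 units with body tissue and 9986 did not. The numbers of called genes are given without and with a term for body tissue in the model, and those of a described gene list with the term where it changed the sum of risen and fallen members by 1.5 times or more. The term was added after the libraries had been seen. Of the genes called without it, 0 at 7 days against group lay among the 2977 genes that differed with body tissue. At 1 day against group 4 did, and between the isolation times 8. The counts without the term therefore say little about those 2977 genes.

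**Figure D1:**
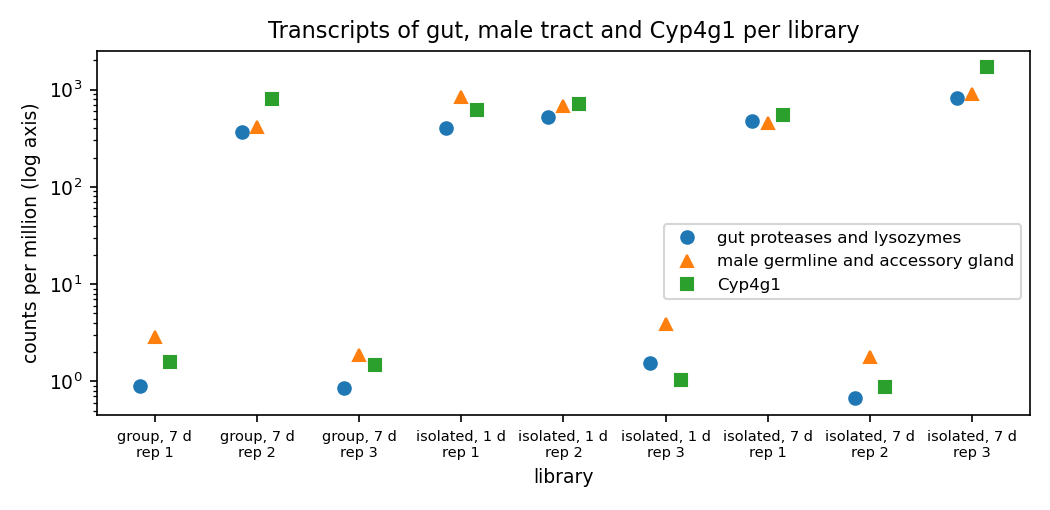
Summed CPM (log axis) of gut and of male tract markers, and CPM of Cyp4g1, in each of the 9 libraries. The 5 libraries with body tissue lie at 367 CPM or higher in all 3 measures and the other 4 at 3.91 CPM or lower.

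Heads of flies kept alone for 7 days differed from those kept in a group in 39 genes, 32 higher and 7 lower. Peptide hormone genes were among them in both directions. Limostatin (Lst, FBgn0034140, chromosome 2R, 16574579 to 16576586), which encodes a hormone that lowers insulin release, rose from 75.8 ± 1.88 to 127 ± 7.37 CPM (SD, n = 3), a log2 change of 0.75. Drosulfakinin (Dsk, FBgn0000500, chromosome 3R, 4189692 to 4190260), a peptide related to cholecystokinin, fell from 81.7 ± 3.70 to 40.3 ± 1.92 CPM (SD, n = 3), a log2 change of -1.02. The satiety gene fit (FBgn0038914, chromosome 3R, 21883924 to 21884454) rose from 20.5 ± 1.79 to 58.7 ± 2.59 CPM, and its exons overlap those of CG31465 on the other strand.

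The strongest evidence at 7 days was for atk, Cyp6a8 and Prx6c, each with an adjusted p of 0.00492 (edgeR quasi-likelihood test, Benjamini-Hochberg). The extracellular matrix gene atk rose by 1.51 (log2, SE 0.0920), from 32.2 ± 3.55 to 91.7 ± 6.26 CPM, and overlaps Uhg8 on the other strand and CG42764 on its own. The cytochrome P450 Cyp6a8 rose by 1.61 (SE 0.104) and the peroxiredoxin Prx6c by 0.94 (SE 0.0641). Sardh, the sarcosine dehydrogenase gene, rose by 1.06 and Tdh, a threonine dehydrogenase gene, by 0.92. The alpha-glucosidase tobi, a target of insulin signalling that overlaps rha on the other strand, rose by 0.82, su(r), an enzyme of pyrimidine breakdown, by 0.72, and Mpc1, a subunit of the mitochondrial pyruvate carrier, by 0.32. Jhe, the juvenile hormone esterase, rose by 1.31. CG9498 rose by 1.28, CG6908 by 0.96, CG9119 by 0.89, CG3984 by 0.89, CG2065 by 0.59, CG15093 by 0.59, MFS9 by 0.48 and CG10553 by 0.42. Jabba, a lipid droplet protein, changed by -0.79, CG9664 by -0.55, CG10175 by -0.31 and mthl10, a receptor of the Methuselah family, by -0.28.

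Among the fixed lists at 7 days, 4 of 72 cytochrome P450 and UDP-glycosyltransferase genes rose and none fell, 6 and 0 when adjusted over the list alone and also with the body tissue term. They were Cyp6a8, Cyp6w1 (0.99), Cyp6a2 (0.61) and Cyp4d21 (0.50). The list rose as a whole with the preset correlation (adjusted p = 0.000265), and had an adjusted p = 0.632 with an estimated correlation. Of 12 Turandot and JAK-STAT genes, TotX (-1.05) and TotC (-1.12) fell and none rose, 7 and 0 when adjusted over the list alone, and 4 and 0 with the body tissue term. The Turandot genes encode stress-induced secreted proteins and are similar in sequence, so reads could be shared between them. That list fell with the preset correlation (adjusted p = 1.19e-08) and had an adjusted p = 0.614 with an estimated correlation. Of 41 neuropeptide genes, Lst rose and Dsk fell, adjusted over all genes and adjusted over the list alone. In all, 19 of 34 lists were called with the preset correlation. With an estimated correlation no list was called by camera, 2 had an unadjusted p under 0.05, and the lowest adjusted p was 0.614. No list passed by fry for direction either (lowest adjusted p = 0.0731, Turandot and JAK-STAT genes). By the mixed test of fry some lists passed and others did not. Those that passed included neuropeptides (mixed fry adjusted p = 2.92e-07), cytochrome P450 and UDP-glycosyltransferase genes (1.02e-06) and Turandot and JAK-STAT genes (0.000194). A pass in the mixed test gives a list no direction. Gut and male tract markers were among the 19 (medians 1.64 and 1.71, adjusted p = 0.00812 and 0.00510), as 2 of 3 libraries of 7 days alone and 1 of 3 group libraries held body tissue, and their adjusted p = 0.678 with an estimated correlation and 0.159 and 0.390 with the body tissue term.

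With a term for body tissue 142 genes were called at 7 days against group, 121 higher and 21 lower, and 38 of the 39 were among them, while with a block for the replicate number edgeR called 0 (637 at an unadjusted p under 0.05) and with upper quartile normalization the call of Dsk was lost. Leaving out 1 library left 14 (group replicate 1), 3 (group replicate 2), 7 (group replicate 3), 31 (isolated replicate 1), 3 (isolated replicate 2) and 4 genes (isolated replicate 3). Of 29 called named genes, atk and tobi passed in all 6 of these fits, Lst passed in 2 (without isolated replicate 1 or 3; highest adjusted p = 0.133 in the others), and 8 passed in none: Dsk, fit and TotC, with highest adjusted p = 0.261, 0.153 and 0.177, and Mpc1, Cyp4d21, CG10175, Cyp6a2 and mthl10.

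Heads of flies kept alone for 1 day differed from those kept in a group in 513 genes, 162 higher and 351 lower. Genes of secreted stress and storage proteins were among those that fell most. Turandot M (TotM, FBgn0031701, chromosome 2L, 5329857 to 5330464) fell from 411 ± 59.8 to 21.7 ± 2.24 CPM (SD, n = 3), and TotC (FBgn0044812, chromosome 3R, 20872988 to 20873580) fell from 1809 ± 171 to 186 ± 11.4 CPM. The larval serum protein gene Lsp1alpha (FBgn0002562, chromosome X, 12490291 to 12492982) fell from 10.7 ± 1.43 to 1.06 ± 0.187 CPM, a call that limma-voom did not make (adjusted p = 0.128). The antifungal peptide gene Drs rose from 26.7 ± 10.8 to 124 ± 38.2 CPM. The gene ple (FBgn0005626, chromosome 3L, 6713356 to 6719525), which encodes tyrosine hydroxylase of dopamine synthesis, rose from 69.1 ± 2.21 to 120 ± 10.9 CPM.

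Transcripts of some muscle and mitochondrial genes rose after 1 day alone. The muscle list, like that of phototransduction, was chosen as a set of cell type markers, to ask whether the samples differ in tissue make-up. Whether its rise came from a larger share of muscle in the heads or from expression within muscle was not tested. Of 23 genes of flight and skeletal muscle 12 rose and none fell, 15 and 0 when adjusted over the list alone. Examples were Act88F (FBgn0000047, chromosome 3R, 15439969 to 15442177), the flight muscle actin, at 1.06 (SE 0.116), Mlp84B at 0.59 and Prm, the paramyosin gene, at 0.43. The muscle list had an adjusted p = 1.81e-13 with the preset correlation, and adjusted p = 0.234 with an estimated correlation. Of 48 oxidative phosphorylation genes 6 rose and none fell, 42 and 0 when adjusted over the list alone, and 20 and 0 with the body tissue term, with a median of 0.32. Fold changes at 1 day went with gene length across genes (Spearman rho = -0.41), and these genes are short (median 951.5 bases against 1782 for all genes). Their median was 0.25 with that trend reduced (remaining rho = -0.19). Their level was 8.24 (log2 CPM) in replicate 3 of 1 day alone, 7.91 in replicates 1 and 2, and 7.71 to 7.73 in the group. Examples were ATPsynC (0.37) and the ADP/ATP carrier gene sesB (0.38), which shares sequence with its neighbour Ant2. That list had an adjusted p = 9.85e-21 with the preset correlation, and adjusted p = 0.448 with an estimated correlation. Mitochondrial transcripts took 7.30% and 7.37% of the counts in replicates 1 and 2 of 1 day alone, 3.41% in replicate 3, and 2.48% to 5.24% in the 6 other libraries. The ribosomal RNA mt:lrRNA alone took 4.31% and 4.52% in replicates 1 and 2 of 1 day alone and 2.27% in replicate 3.

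Some genes of lipid use and of photoreceptors fell after 1 day alone. Of 18 genes of fatty acid oxidation and lipolysis 4 fell and none rose, 9 and 0 when adjusted over the list alone. They included the triglyceride lipase gene bmm (FBgn0036449, chromosome 3L, 14776496 to 14786412) at -0.64 and the acyl-CoA dehydrogenase gene Mcad, which overlaps CG7457 on the other strand, at -0.46. The list had an adjusted p = 9.24e-07 with the preset correlation, and adjusted p = 0.447 with an estimated correlation. Of 22 genes of the fasting and FOXO response 6 fell and none rose, 9 and 4 when adjusted over the list alone, among them Pepck2 (-1.05), bmm and AkhR (-0.46), the receptor of adipokinetic hormone. Their list had an adjusted p = 0.00134 with the preset correlation, and adjusted p = 0.364 with an estimated correlation. Of 20 genes of fatty acid and triglyceride synthesis 1 rose and 2 fell, 1 and 7 when adjusted over the list alone. Those that fell were the lipid droplet gene Lsd-2 (-0.55) and the ATP citrate lyase gene ATPCL (-0.48), which overlaps CG8320 and Tmem131 on the other strand. Of 33 phototransduction genes 4 fell and none rose, 13 and 0 when adjusted over the list alone, among them the light-activated channel gene trpl (-0.69) and pinta (-0.63). This list had an adjusted p = 9.77e-09 with the preset correlation, and adjusted p = 0.364 with an estimated correlation. These genes are long (median 2476 bases against 1782 for all genes), and their median moved from -0.23 to -0.18 with the length trend reduced. At 7 days against group the list fell too with the preset correlation (median -0.12, camera adjusted p = 5.74e-08), with no member called. With an estimated correlation its adjusted p there was 0.632.

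Of the 12 Turandot and JAK-STAT genes 6 fell and none rose after 1 day, 6 and 2 when adjusted over the list alone, with TotM at -4.24 (SE 0.282), TotC at -3.28, TotA at -2.83 and TotX at -2.02. Camera gave the list an adjusted p = 4.08e-05 with the preset correlation, and adjusted p = 0.402 with an estimated correlation. Of 72 cytochrome P450 and UDP-glycosyltransferase genes 4 rose and 8 fell, 5 and 22 when adjusted over the list alone, and 5 and 13 with the body tissue term, with Cyp6w1 at 0.89, Cyp4d21 at 0.50 and Cyp4e3 at -0.78. That list had an adjusted p = 9.86e-05 with the preset correlation, and adjusted p = 0.448 with an estimated correlation. Of 52 cuticle protein genes 3 rose and 2 fell, 7 and 2 when adjusted over the list alone and also with the body tissue term, with Cpr47Ee at 0.74, Cpr100A at 0.72 and Cpr11B at -1.19, and the list median was 0.47 (adjusted p = 0.00147 with the preset correlation, adjusted p = 0.448 with an estimated correlation). Of 35 genes of odorant-binding proteins and antennal binding proteins 4 fell and none rose, 5 and 0 when adjusted over the list alone. Among them were Obp99b (-1.26) and the antennal protein gene a10 (-2.37). That list had an adjusted p = 0.00592 with the preset correlation, and adjusted p = 0.655 with an estimated correlation. Of 31 antimicrobial peptide genes 2 rose, Drs (2.21, SE 0.372) and the bomanin BomBc1 (1.77), and 1 fell, or 4 and 4 when adjusted over the list alone. As a whole this list did not pass (adjusted p = 0.179). With the body tissue term 8 rose and 4 fell and the list had an adjusted p = 0.00429 with the preset correlation and adjusted p = 0.662 with an estimated correlation. Of its 31 genes, 12 differed by at least 0.5 log2 units with body tissue.

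Other called genes after 1 day were the corneal lens gene retinin (1.44), Srg1 (1.94, with CG7016 on the other strand), fit (1.79), Jhe (from 6.40 ± 1.11 to 15.2 ± 1.34 CPM) and the heat shock cognate gene Hsc70-1 (0.61) on the higher side. Those on the lower side included Diedel (-4.07), CheA87a (-2.48, with Lip3 on the other strand), CG5966 (-1.83), CG12256 (-1.77, with an antisense RNA on the other strand), Arc1 (-1.53), CG13796 (-1.02), P5cr-2 (-0.93), cDIP (-0.77), the transcription factor gene lz (-0.65) and tobi (-0.48). The clock gene tim changed by -0.35 (adjusted p = 0.0173), while per changed by 0.17 (adjusted p = 0.105).

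At 1 day 13 of 34 lists were called with the preset correlation. None was called by camera with an estimated correlation, where 4 had an unadjusted p under 0.05 and the lowest adjusted p was 0.234. By fry for direction the lists described above for 1 day passed (lowest adjusted p = 0.000759, Turandot and JAK-STAT genes), with some exceptions. These were fatty acid and triglyceride synthesis (fry adjusted p = 0.0576), odorant-binding and antennal binding proteins (0.0621) and antimicrobial peptides (0.680). All of these exceptions passed the mixed test of fry (adjusted p = 0.000153, 1.68e-05 and 2.87e-05). Gut and male tract markers were among the 13 lists (medians 1.14 and 1.82, camera adjusted p = 0.0281 and 0.00651 with the preset correlation). With the body tissue term the gut list did not pass (adjusted p = 0.880), but the male tract list still rose (median 0.84, adjusted p = 0.00220). The term marks only the presence of the tissue. With a term for body tissue 728 genes were called, 304 higher and 424 lower, and 455 of the 513 were among them, while 133 were called with only the libraries of the groups compared and 162 with a block for the replicate number. Leaving out 1 library left 151 (group replicate 1), 190 (group replicate 2), 170 (group replicate 3), 301 (isolated replicate 1), 255 (isolated replicate 2) and 881 genes (isolated replicate 3), and of 45 called named genes 30 passed in all 6 of these fits, with bmm and Hsc70-1 in 1 and Drs, BomBc1, ATPsynC, sesB and tim in 2 of them.

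**Figure D2:**
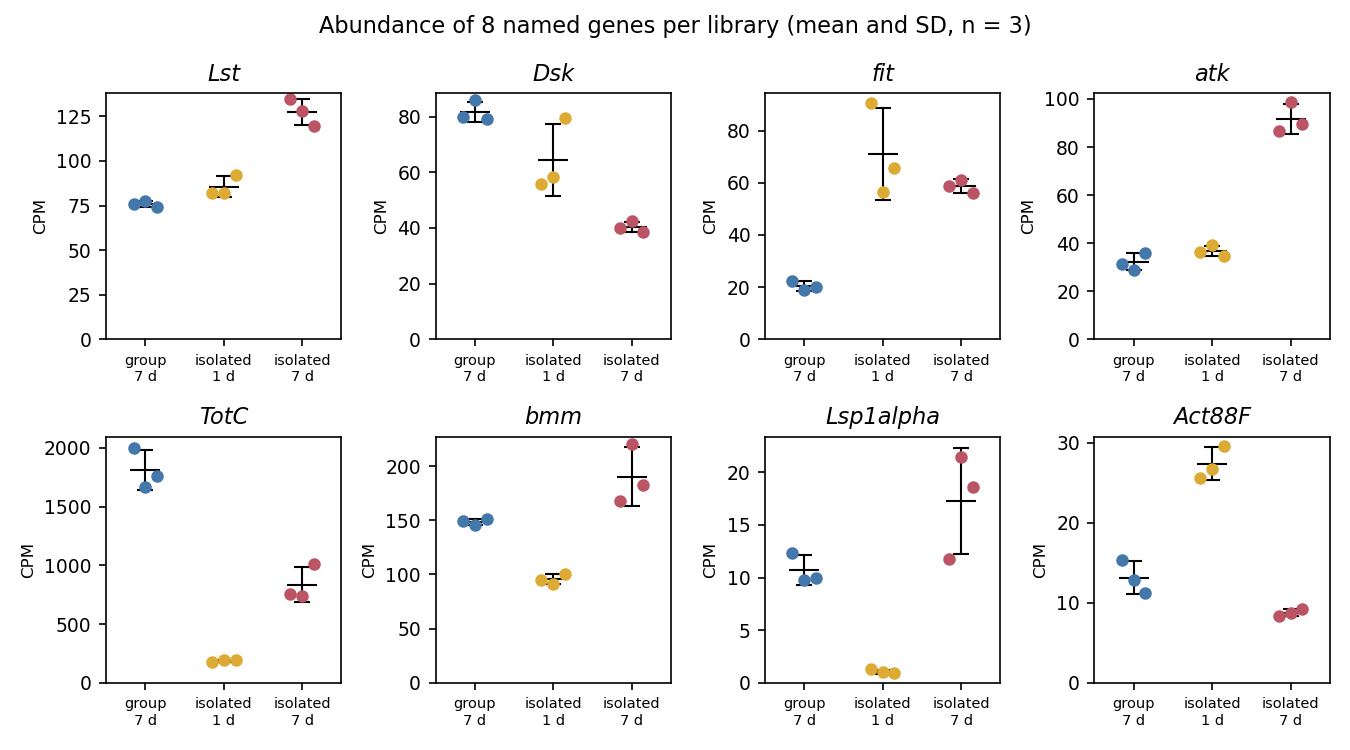
Abundance in CPM of 8 named genes in each library of the 3 groups, with mean and SD (n = 3). TotC and Lsp1alpha were lowest after 1 day alone, Lst and atk were highest and Dsk lowest after 7 days alone, and fit was higher than in the group at both times.

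Heads after 7 days alone differed from those after 1 day alone in 599 genes, 403 higher and 196 lower at 7 days. Lsp1alpha rose from 1.06 ± 0.187 to 17.3 ± 5.0 CPM (SD, n = 3; adjusted p = 0.0812 with limma-voom), TotM from 21.7 ± 2.24 to 134 ± 43.5 CPM and bmm from 95.5 ± 4.66 to 190 ± 27.3 CPM. The muscle actin gene Act88F fell from 27.3 ± 2.06 to 8.78 ± 0.401 CPM and Drs from 124 ± 38.2 to 18.7 ± 3.11 CPM. Of the 513 genes called at 1 day against group, 314 were called between the isolation times in the opposite sense; both comparisons use the same 3 libraries of 1 day alone, and no chance value was computed for this overlap. Of the 513 genes, 23 were called at 7 days against group in the same direction as at 1 day.

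Some genes of lipid and carbohydrate metabolism rose at 7 days against 1 day. Of 18 genes of fatty acid oxidation and lipolysis 7 rose and none fell, 12 and 0 when adjusted over the list alone, and 11 and 0 with the body tissue term, with bmm at 0.99 (SE 0.0954) and Mcad at 0.57. As a whole the list had an adjusted p = 7.79e-11 with the preset correlation, and adjusted p = 0.237 with an estimated correlation. Of 20 genes of fatty acid and triglyceride synthesis 5 rose and none fell, 10 and 1 when adjusted over the list alone, and 8 and 0 with the body tissue term, with Lsd-2 and ATPCL both at 0.48. The list had an adjusted p = 5.92e-05 with the preset correlation, and adjusted p = 0.366 with an estimated correlation. Of 23 genes of glycolysis and trehalose or glycogen metabolism 6 rose and none fell, 8 and 0 when adjusted over the list alone, with the gluconeogenic gene fbp at 0.52 and UGP, which overlaps CG32040 and PGRP-LF on the other strand, at 0.50. As a whole that list did not pass (adjusted p = 0.177). Of 14 amylase and maltase genes 4 rose and none fell, both adjusted over all genes and adjusted over the list alone, and 6 and 0 with the body tissue term, with tobi at 1.3 (SE 0.0638) and Amy-d at 1.27. That list had an adjusted p = 0.00293 with the preset correlation, and adjusted p = 0.453 with an estimated correlation; 9 of its 14 genes differed by at least 0.5 log2 units with body tissue. Of 22 genes of the fasting and FOXO response 6 rose and 2 fell, 7 and 2 when adjusted over the list alone, with Pepck2 at 1.12. Those that fell were Thor, a repressor of translation (-0.51), and the cytokine gene upd2 (-3.08), named after its value had been seen. The fasting list had an adjusted p = 0.000431 with the preset correlation, and adjusted p = 0.237 with an estimated correlation.

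Of 72 cytochrome P450 and UDP-glycosyltransferase genes 15 rose and 1 fell at 7 days against 1 day, 18 and 2 when adjusted over the list alone, with Cyp4e3 at 0.87, Cyp6a23 at 0.62 and Cyp9b2 at 0.57. Camera gave the list an adjusted p = 4.32e-11 with the preset correlation, and adjusted p = 0.237 with an estimated correlation. Of the 12 Turandot and JAK-STAT genes 5 rose, among them TotM (2.62), TotC (2.17), TotA (1.87) and TotX (0.97), and 1 fell, with 5 and 3 when adjusted over the list alone. The gene that fell was again upd2. This list had an adjusted p = 0.00293 with the preset correlation, and adjusted p = 0.453 with an estimated correlation.

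Of 23 muscle genes 12 fell and none rose at 7 days against 1 day, 16 and 0 when adjusted over the list alone, with Act88F at -1.64 (SE 0.118), the myosin light chain gene Mlc1 at -0.64 and Mlp84B at -0.54. As a whole the list had an adjusted p = 1.75e-16 with the preset correlation, and adjusted p = 0.144 with an estimated correlation. The mean level of the list was 6.85 to 7.27 (log2 CPM) in the libraries of 1 day alone, and replicate 1 of 7 days alone, which held body tissue, lay within that range (6.88) while replicates 2 and 3 lay below it (up to 6.58). Of these 23 genes, 2 differed by at least 0.5 log2 units with body tissue. Here too the share of muscle in the samples was not told apart from expression within muscle. Of 48 oxidative phosphorylation genes 3 fell and none rose, 28 and 0 when adjusted over the list alone, and 11 and 0 with the body tissue term, with ATPsynC at -0.37 and sesB at -0.38. That list had an adjusted p = 2.19e-20 with the preset correlation, and adjusted p = 0.453 with an estimated correlation. Its median moved from -0.28 to -0.24 with the length trend reduced. The mitochondrial share of the counts was highest in replicates 1 and 2 of 1 day alone (7.30% and 7.37%). It did not follow the list, as replicate 3 of 1 day alone had the highest list level (8.24 log2 CPM) and a share of 3.41%. Of 52 cuticle protein genes 5 fell and none rose, 10 and 0 when adjusted over the list alone, and 10 and 1 with the body tissue term, with Cpr100A at -1.10 and Cpr47Ee at -0.78. The cuticle list had an adjusted p = 3.46e-05 with the preset correlation, and adjusted p = 0.293 with an estimated correlation. Of 31 antimicrobial peptide genes 4 fell and none rose, 11 and 1 when adjusted over the list alone, and 12 and 2 with the body tissue term, with AttD at -4.08 and Drs at -2.73 (SE 0.38). The list had an adjusted p = 6.24e-05 with the preset correlation, and adjusted p = 0.575 with an estimated correlation.

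Of 41 neuropeptide genes 1 rose and 5 fell at 7 days against 1 day, 1 and 6 when adjusted over the list alone. Lst rose by 0.57 (SE 0.0594), and Dsk (-0.68) and CNMa (-1.24) were among those that fell. Camera gave the list an adjusted p = 0.0415 with the preset correlation, 0.0531 with the body tissue term, and adjusted p = 0.849 with an estimated correlation. Other called genes were CG5966 (2.12), CG12256 (1.74), atk (1.32), Diedel (2.63) and Obp99b (0.70) on the higher side, and CG11458 (-4.15), CG4000 (-1.43, with an antisense RNA on the other strand), the chitin deacetylase gene serp (-1.25), retinin (-1.18) and ple (-0.80) on the lower side. The clock gene tim rose by 0.35 (adjusted p = 0.0170), and per, which overlaps dyw on the other strand, changed by -0.24 (adjusted p = 0.0331).

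Between the isolation times 18 of 34 lists were called with the preset correlation. None was called by camera with an estimated correlation, where 5 had an unadjusted p under 0.05 and the lowest adjusted p was 0.144. By fry for direction the lists described above for these times passed (lowest adjusted p = 0.00153, muscle genes), with some exceptions. These were oxidative phosphorylation (fry adjusted p = 0.0666), glycolysis and trehalose or glycogen metabolism (0.156), antimicrobial peptides (0.223) and neuropeptides (0.396). All of these exceptions passed the mixed test of fry (adjusted p = 0.0132, 1.40e-05, 0.000127 and 6.71e-08). With a term for body tissue 895 genes were called, 582 higher and 313 lower, and 562 of the 599 were among them, while 32 were called with only the libraries of the groups compared and 126 with a block for the replicate number. Leaving out 1 library left 341, 244 and 1167 genes (replicates 1, 2 and 3 of 1 day alone) and 328, 101 and 72 genes (replicates 1, 2 and 3 of 7 days alone), and of 42 called named genes 22 passed in all 6 of these fits, with tim in 1, AttD and Dsk in 2, and per, Thor, ATPsynC and sesB in 3 of them.

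**Figure D3:**
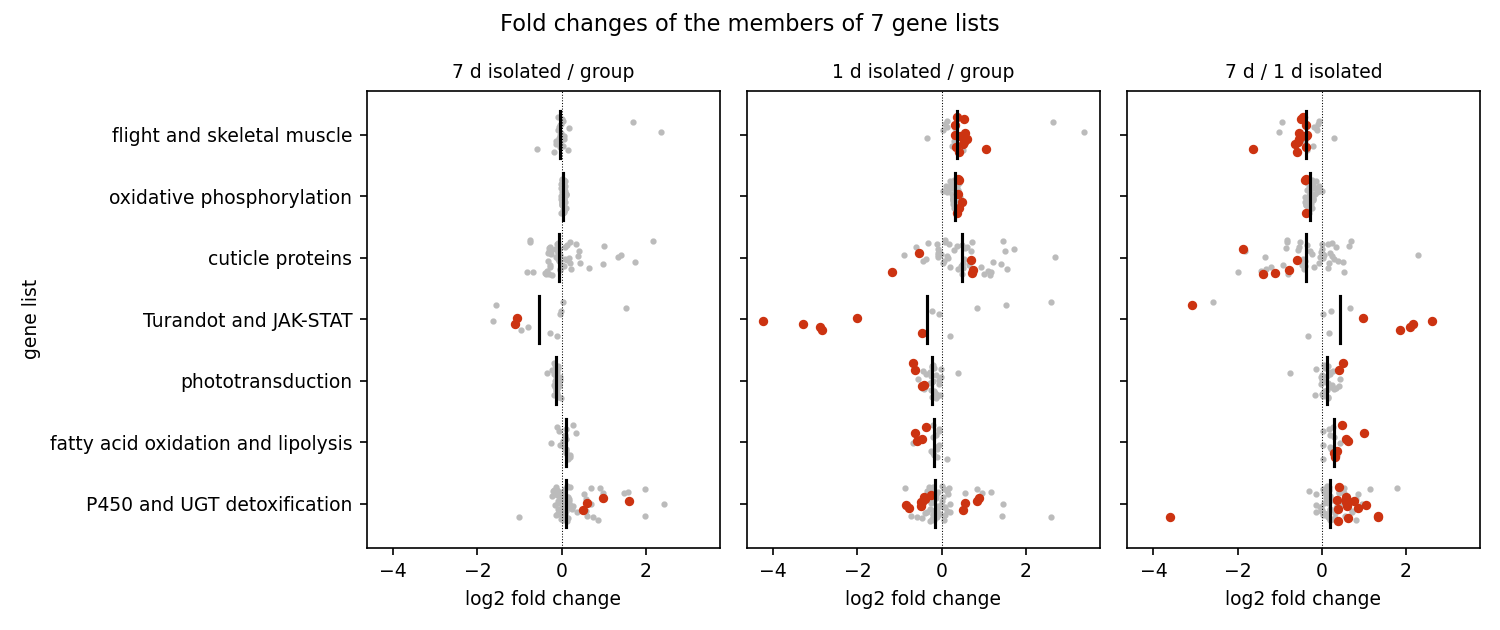
Log2 fold changes of the tested members of 7 gene lists in the 3 comparisons, with called genes in red and the list median as a black line. Of 23 muscle genes 12 rose at 1 day against group and 12 fell at 7 days against 1 day, and 7 of 18 genes of fatty acid oxidation and lipolysis rose at 7 days against 1 day.

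Some genes tied to social experience, rhythm or nutrition were named whatever their values. At 7 days against group, Cyp6a20 changed by -0.10 (adjusted p = 0.880), Obp69a by -0.28 (adjusted p = 0.880), to by 0.36 (adjusted p = 0.430), Hr38 by 0.12 (adjusted p = 0.947), Thor by -0.25 (adjusted p = 0.696), per by -0.08 (adjusted p = 0.880) and tim by -0.0027 (adjusted p = 0.993). At 1 day, Lst changed by 0.17 (adjusted p = 0.168), Dsk by -0.34 (adjusted p = 0.211), Cyp6a20 by -0.24 (adjusted p = 0.102), Obp69a by -0.42 (adjusted p = 0.194), to by 0.18 (adjusted p = 0.462), Hr38 by 1.01 (adjusted p = 0.292) and Thor by 0.26 (adjusted p = 0.204). The Hr38 value at 1 day rested on replicate 2 of 1 day alone, at 32.5 CPM against 11.5 and 8.70 CPM in replicates 1 and 3, and was 0.22 without it. Exons of Obp69a overlap CG32104 and those of Hr38 overlap CG2617 on the other strand. Of 28 genes of social experience, aggression and courtship Dsk alone changed at 7 days against group, adjusted over all genes and adjusted over the list alone. That list did not pass at 7 days (adjusted p = 0.0966) or at 1 day (adjusted p = 0.419) against group. Between the isolation times it fell with the preset correlation (adjusted p = 0.0184), with an adjusted p = 0.453 with an estimated correlation, and 1 of its genes, Dsk, fell and none rose, 2 and 0 when adjusted over the list alone and also with the body tissue term.

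In the F test of any difference among the 3 groups 582 genes changed, and 902 with a term for body tissue. At both isolation times against group, 17 genes were called higher (0.400 expected of independent lists) and 6 lower (0.190 expected), while tobi was higher at 7 days and lower at 1 day. Across the 12963 genes, which are not independent replicates, the log2 changes at 7 days and at 1 day correlated at Pearson r = 0.852 and Spearman rho = 0.610. Both comparisons share the 3 group libraries. Simulations that drew all 9 libraries anew without group differences, with the simulated controls shared in the same way, gave r = 0.846. With a term for body tissue r was 0.581 (simulated 0.594), and among the 9986 genes without a body effect it was 0.255 (simulated 0.516). The covariance was 0.436 for all genes (simulated 0.191), 0.102 with the term (simulated 0.0497) and 0.0153 without body genes (simulated 0.0147). Simulated unchanged groups gave no gene called at both times by edgeR, but 3 controls cannot be divided between the comparisons, so part of the 23 shared calls could still come from the shared libraries.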

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

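The tests of the body tissue in 5 libraries against reads exchanged between libraries and against housing, and the tests of the 1-day calls and of the smaller count at 7 days with body tissue or gene length, were chosen after those results had been seen. Leaving out replicate 3 of 1 day alone was a setting fixed beforehand, but its use as a test of the 1-day calls was chosen afterwards. The tests on Malpighian tubule genes and on other splits of the samples were set down before their results were known.

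Between 7 days and 1 day alone 599 genes differed (edgeR quasi-likelihood, Benjamini-Hochberg). Both times shared a single control, the group of 7 days, so this is the direct comparison of the isolated flies, in which the age of the flies, not given in the labels, is not separated from the time alone. Of 73 genes named in a comparison against group, 50 were called in this test, 35 higher and 15 lower at 7 days. The log2 changes of 7 days against 1 day alone among the higher genes were Lsp1alpha (4.02), Diedel (2.63), TotM (2.62), TotC (2.17), CG5966 (2.12), TotA (1.87), CG12256 (1.74), CheA87a (1.53) and atk (1.32). They were smaller in tobi (1.3), a10 (1.23), CG9119 (1.22), Pepck2 (1.12), Sardh (1.11), CG13796 (1.00), bmm (0.99), TotX (0.97) and Cyp4e3 (0.87). Next came Cyp6a8 (0.78), cDIP (0.76), Obp99b (0.70), P5cr-2 (0.66), Lst (0.57), Mcad (0.57), trpl (0.50), lz (0.49) and Lsd-2 (0.48). The smallest were ATPCL (0.48), Prx6c (0.45), pinta (0.40), CG15093 (0.39), tim (0.35), CG9664 (0.32), mthl10 (0.29) and CG10175 (0.24). Among the lower genes they were Drs (-2.73), Act88F (-1.64), BomBc1 (-1.48), retinin (-1.18), Srg1 (-1.15), Cpr100A (-1.10), ple (-0.80) and Cpr47Ee (-0.78), followed by Dsk (-0.68), Mlp84B (-0.54), Thor (-0.51), sesB (-0.38), Prm (-0.38), ATPsynC (-0.37) and per (-0.24). The real split of the 6 libraries gave 599 genes (2261 with an unadjusted p under 0.05) and the highest of the 9 other splits gave 0 by edgeR (up to 1555 with an unadjusted p under 0.05). As many genes came in 1 of the 10 splits, and 10 splits are too few for a share under 0.05.

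Gut and male tract transcripts stood at 775 to 1721 CPM in 5 libraries and at 2.47 to 5.46 CPM in 4. RNA of other body parts collected with the heads is a candidate explanation. Of the Malpighian tubule genes Uro, ZnT35C and Irk3, which no other list held and which passed the filter on low counts, Uro and ZnT35C were higher in the 5 libraries (7.58 and 3.86 on the log2 scale) and Irk3 was not (-0.03), with a median of 3.86. Reads exchanged between libraries of the series are argued against, since the lowest of the 5 libraries held 45% of the level of the highest and no single library stood far above the others as their source. Housing as the cause is argued against by all 3 groups holding both kinds of library, and where the tissue came from stays open.

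The 513 genes called at 1 day against group may owe something to uneven body tissue, to replicate 3 of 1 day alone or to gene length. Of these calls 88.7% held with a term for the presence of body tissue. However, 4 of the 513 lay among the 2977 genes that differed by at least 0.5 log2 units with body tissue. A high share was therefore likely in advance, and it cannot exclude that presence as a cause. Without replicate 3 of 1 day alone 82.5% held, which argues against that library as the whole cause. Uneven amounts among the libraries with body tissue were not modelled, and male tract markers still rose with the term (median 0.84, camera adjusted p = 0.00220, preset correlation). With the length trend reduced 82.8% held, but fold changes still went with length (Spearman rho = -0.19 after -0.41), so this test cannot exclude gene length. The age of the flies at collection, not given in the labels, was not tested and stays open beside isolation itself, as flies kept alone for 1 day could have been younger. Library totals, lower in all libraries of 1 day alone than in the others, were not tested as a cause either. The same holds for a different share of muscle or photoreceptors in the heads of 1 day alone, which stays open. The real split gave 513 genes (2401 with an unadjusted p under 0.05) and the highest of the 9 other splits gave 0 by edgeR, although the split that follows body tissue had 3094 with an unadjusted p under 0.05 and the others up to 768. As many genes came in 1 of the 10 splits, too few for a share under 0.05.

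Fewer genes were called at 7 days (39) than at 1 day (513) against group, and spread added by body tissue could hide calls at 7 days. With the body tissue term the 1-day count was still 5.13 times the 7-day count (728 and 142), which argues against spread from the presence of that tissue as the whole cause. Spread from uneven amounts among the libraries that held it was not modelled. A smaller or more variable response at 7 days and the age of the flies stay open. The split of the 6 libraries that parts those with body tissue from those without gave 1887 genes against 39 for the real split, which points to the tissue as a structure of the samples, and the 8 other splits gave 0 by edgeR (up to 221 with an unadjusted p under 0.05). As many genes as in the real split came in 2 of the 10 splits, too few for a share under 0.05.

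For the lists, the real split and the highest other split gave 19 and 19 at 7 days against group (as many in 2 of 10 splits), 13 and 17 at 1 day (6 of 10) and 18 and 18 between the isolation times (2 of 10), and 10 splits are too few for a share under 0.05. For the F test the real split gave 582 genes and the highest of 99 other drawn splits gave 170. As many came in 1 of 100 splits, a share under 0.05, which argues against a random grouping of the 9 libraries. The other splits with the most genes (170, 146 and 135) each kept the 3 libraries of 1 day alone together. This result therefore does not by itself tell 7 days alone from the group.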

How the results depend on the processing

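The settings with body tissue and with gene length were chosen after seeing the data. In every setting where they were tested, all 39, 513 and 599 called genes (7 days against group, 1 day against group, 7 days against 1 day) kept their direction, while the counts moved. With only the libraries of the groups compared the counts were 64, 133 and 32, and with DESeq2 312, 1498 and 1478, with 1820 in the F test. With a block for the replicate number they were 0, 162 and 126, with 117 in the F test; at 7 days 637 genes still had an unadjusted p under 0.05 in edgeR. The block costs residual degrees of freedom. With no filter 348 genes were called between the isolation times and 356 in the F test, and with 1 CPM in 3 libraries 61 at 7 days. With the body tissue term 142 genes were called at 7 days and 902 in the F test. Without body genes the counts were 171, 1053 and 1086, with 1195 in the F test, and with the length trend reduced 86, 830 and 927, with 930 in the F test. The 4 libraries without body tissue gave 827, 5606 and 4718 genes, with 5683 in the F test, on 1 residual degree of freedom; the 5 with it gave 5, 87 and 320, with 216 in the F test, on 2. In both, a group with a single library was assumed to vary like the others. Leaving out a single library gave 3 to 31, 151 to 881 and 72 to 1167 genes, 90 to 1084 in the F test, 16 to 18, 12 to 15 and 15 to 21 lists, and r from 0.735 to 0.988. With an estimated correlation 0, 0 and 0 lists were called by camera (2, 4 and 5 at an unadjusted p under 0.05), and with the body tissue term as well 0, 0 and 0 (3, 6 and 6). Without body genes 10 lists were called at 7 days. The correlation of fold changes was 0.581 with the body tissue term and 0.256 without body genes. Except where fewer libraries or genes were fitted, the cause was not tested. Of 116 calls of named genes, 55 were lost with the block, 41 with only the groups compared and 8 with no filter. With limma-voom 5 were lost, Lsp1alpha and a10 at 1 day against group, and Lsp1alpha, Diedel and AttD at 7 days against 1 day. Upper quartile normalization and the reduced length trend lost 3 each, and RLE, DESeq2 and the body tissue term lost 0. DESeq2 also called 4 results that the main fit did not, to at 7 days and Lst, Cyp6a20 and per at 1 day against group. No direction turned.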

Other observations

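The test of both lists in the next paragraph was set down before their values were known, after enzymes of this kind had been seen among the called genes.

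Sardh and Tdh, called at 7 days against group, belong to glycine and one-carbon metabolism, and a hypothesis was that other genes of that pathway and of purine synthesis were higher too. Of 15 further genes of one-carbon, glycine and methionine metabolism 13 were higher after 7 days alone than in the group, with a median log2 change of 0.34 and an adjusted p of 8.53e-09 (camera, preset correlation, body tissue term), and 4 passed singly. Of 8 further purine synthesis genes 6 were higher, with a median of 0.23 and an adjusted p of 4.43e-06, and 3 passed singly. With an estimated correlation the lists had an adjusted p = 0.0652 and adjusted p = 0.0686. A joint rise may be present but does not pass that test, even with the lighter adjustment. Without the body tissue term the adjusted p values were 2.38e-05 and 5.92e-05 with the preset correlation, and adjusted p = 0.131 for both with an estimated correlation, and no gene of either list passed singly by edgeR. At 1 day against group neither list passed (adjusted p = 0.374 and 0.160 with the body tissue term), and singly 2 of the 15 and 3 of the 8 genes were lower and 0 higher by edgeR with that term. Without the term 1 of the 8 purine synthesis genes was higher and 0 lower, and 0 of the 15 passed. At 7 days against 1 day, 6 and 5 were higher and 0 lower by edgeR with that term.

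Of the 599 genes called between the isolation times, 269 were called against group at neither time.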
